A study of Mus musculus with 2 samples.

How the data were processed

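Gene expression was measured in bone marrow-derived macrophages from calpain-6 wild-type mice (Capn6-Wt) and calpain-6-deficient mice (Capn6-Ko), with 1 array per group. Per the labels' protocols, femoral marrow cells of male mice were cultured with 10% serum, 50 ng/mL of M-CSF and 10 ng/mL of TNF-α, unbound cells were washed off, and total RNA was extracted with Trizol and labelled with Cy3. The labels name day 3 of culture in one field and day 4 in another. The series design text gives 4 mice, pooled, and does not say whether this is the number per group.

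The deposited scanner files hold the intensity of each spot on a linear scale, made by the authors with Agilent Feature Extraction 10.10.1.1, per the file headers. The column used here is the processed signal, which that software has background-subtracted and kept above 0 within each array, with no scaling between arrays. Both arrays lay on the same slide and were scanned together, per the file headers, so slide and scan do not differ between the groups. The design of the array is annotated on the mouse build mm9. The authors' value table is also an intensity on a linear scale, uncentred and with no direction. Set against the scanner values, each of its 59305 rows was the processed signal times 1 constant per array, 2.39 for Capn6-Wt and 2.42 for Capn6-Ko, which brings the 75th percentile of both arrays to 901. Its column medians were 53.0 and 50.7. How the authors chose the constants is not given in the sources used here.

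Each array has 62976 spots, of which 59305 are not controls and hold 55681 distinct probes. Control spots were left out, and so were spots flagged as outliers, 161 on the Capn6-Wt array and 136 on the Capn6-Ko array. No spot was saturated. The log2 of the processed signal was taken relative to the 75th percentile of the array over non-control spots, and spots of a probe were averaged. A probe counted as measured when most of its spots were well above background on both arrays. Of 55678 probes left, 28682 carried a RefSeq accession and 27232 matched a gene symbol in a RefSeq gene table of the assembly GRCm38.p6, which was used for names and for the order of neighbouring genes only. The other 28446 probes stayed unnamed. The value of a gene is the mean log2 difference, Capn6-Ko minus Capn6-Wt, over its measured probes. This gave 12875 genes of 20660 on the array. Of 3331 genes with more than 1 measured probe, 1526 had probes of different sign, and 6 had probes past 1.25-fold in opposite directions.

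With 1 pooled array per group there are no residual degrees of freedom, so no test between genotypes was run and no p-value is given. Genes were counted by a fixed size of 2-fold. The ± after a log2 difference is the SD expected from spot-to-spot spread, taken from 263 measured probes with at least 5 of their 10 planned spots per array in 8 bins of level, and scaled to the number of spots of the gene. It covers spotting and scanning only, not mice, culture, RNA extraction or labelling. The number of genes that this spread gives past a size was estimated from 22059 pairs of spots of the same probe on the same array, by level. The pairs are single spots, not means over probes. They can include spots not well above background, of probes whose other spots mostly are. Both can raise the number, mainly for dim genes. The number of arrays limits the precision of every value.

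Gene lists, 38 in all, were written before the data were examined, as was the rule for named genes. The median difference of each list was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean level. A list stood apart at or below percentile 2.5 or at or above percentile 97.5. The 37 lists with at least 5 measured genes were placed in this way. The percentile describes these 2 arrays and is not a p-value. It treats genes as independent, whereas genes of a pathway vary together between any pair of cultures.

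Named genes are every measured calpain, and the 12 highest and 12 lowest differences among genes above the median level whose probes have the same sign. They also include the 5 largest bounds per direction among genes well above background on 1 array only, the 4 members furthest in the direction of each list that stood apart, and 5 genes of the lipid uptake and splicing themes (Rac1, Cwc22, Abca1, Cd36, Msr1). Members against the direction of such a list, or of any other list, were to be named only at 2-fold, which none reached. Results for 1 gene list and for some genes under this rule are not reported here. Other genes named in the text were chosen after their values were seen. For a gene well above background on 1 array only, the fold is a bound. It sets the bright array against the higher of the dim probe's own level and the lowest signal well above background on the dim array.

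The scripts ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and in R 4.3.3 with limma 3.58.1 for quantile normalization and normexp. They were tested on simulated arrays of 12875 genes made from the real levels and the spot error. For the simulated Capn6-Ko against Capn6-Wt comparison, 100% of genes changed by a log2 of 1.5 and 100% of those changed by 2.0 were found at 2-fold, and 0 of 12075 unchanged genes were. In the same simulation 374 unchanged genes passed 1.25-fold, 100% of lists of 30 genes shifted by -0.4 were found lower, and 3.5% of unchanged lists stood apart. The simulated noise was normal, with the median spot variance of each level bin, so it lacks the large strays of real spots. Real spot pairs give 11.7 genes past 2-fold and 571 past 1.25-fold over 12875 genes, numbers that may be too high for the reasons given above. The 0 calls at 2-fold therefore do not carry over to the real arrays.

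Alternatives were quantile normalization, the median of measured probes as centre, the authors' value table, no filter on dim probes, only probes above the median level, flagged spots kept, the brightest probe or the median over probes of a gene, random lists not matched on level, and the list mean. The planned normexp correction on mean pixel signals could not be run, because the deposited files hold median pixel signals. It was run with an offset of 50 on the median signals, a choice made after seeing the files, as were the counts at 1.25-fold and 1.5-fold.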

Results

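The series measured mRNA in cultured bone marrow-derived macrophages, cells grown from marrow with the growth factor M-CSF, from mice with and without calpain-6. Calpain-6 is a member of the calpain protein family that lacks the catalytic cysteine of the proteases. TNF-α, an inflammatory cytokine, was in the medium of both cultures. Each group was 1 array of pooled cells, so there were no replicates, and every value describes these 2 RNA pools. On the Capn6-Wt array 30656 of 59305 spots (51.7%) were well above background, and on the Capn6-Ko array 31304 (52.8%). The 75th percentile of the processed signal was 377 and 372, the local background had a median of 27 and 29, and the median spread of replicated spots was 4.66% and 4.79%. Across measured probes the log2 levels of the arrays had a Pearson r of 0.998, which is across genes, not samples.

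The targeted gene was near the detection limit in both cultures. Capn6 has a single probe on the array (A_52_P474089), with a signal of 3.93 on the Capn6-Wt array and 8.65 on the Capn6-Ko array. It was not well above background on either, so no fold is given. This probe therefore does not check the labels, and whether it lies in the deleted part of the gene is not given in the sources used here. The male labels could be checked in part. The Y-linked genes Ddx3y, Eif2s3y and Uty were measured on both arrays, with differences of 0.029, 0.14 and 0.042, and the probes of Xist, the RNA that silences the inactive X chromosome, were not well above background on either.

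The comparison of Capn6-Ko with Capn6-Wt asks what the loss of calpain-6 changes in the macrophage transcriptome. Stromal fibroblast and extracellular matrix genes were lower in the Capn6-Ko pool, with a median log2 difference of -0.44, the largest shift among the 38 lists. Genes of the interferon response, MHC class II, chemokine receptors, the cell cycle and platelets were higher by smaller amounts. Most genes were at nearly the same level, with a median log2 difference of -0.0056 and an SD over 12875 genes of 0.18. Among the 6437 genes above the median level the SD was 0.10, and differences ran from -0.65 to 0.84. In that brighter set 44 genes were at least 1.25-fold higher and 57 at least 1.25-fold lower, where pairs of spots of the same probe on 1 array give 4.22 in all. At 1.5-fold the counts were 5 higher and 9 lower, against 0 from spot pairs. Over all 12875 genes 340 were higher and 712 lower at 1.25-fold, where spot pairs give 571 in all, and 43 higher and 162 lower at 1.5-fold, where they give 117. The numbers from spot pairs over all genes may be too high, since the pairs are not averaged over probes and include some dim spots. These sizes were added after the data were seen.

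**Figure D1:**
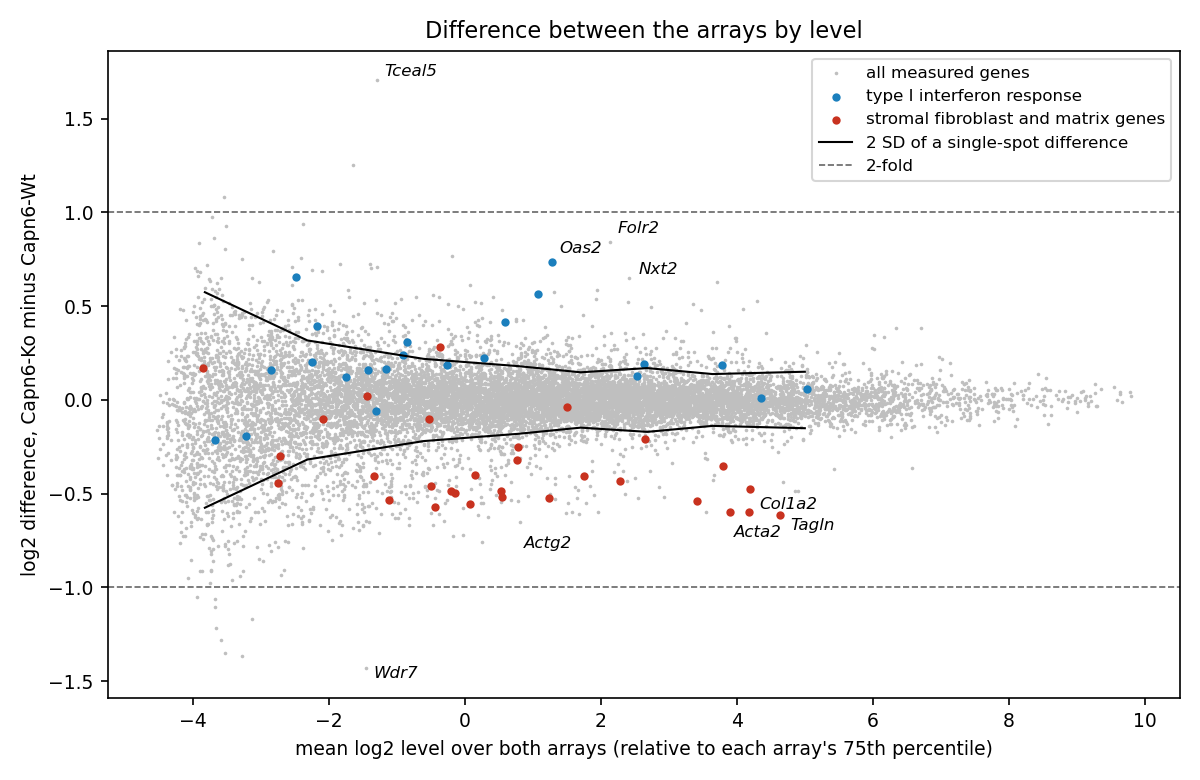
Each point is 1 of 12875 genes, with the mean log2 level over both arrays on the x axis and the log2 difference, Capn6-Ko minus Capn6-Wt, on the y axis; red points are the stromal and matrix list, blue points the type I interferon list, solid lines 2 SD of a single-spot difference by level, and dashed lines 2-fold. Of the 30 red points, 27 lie below 0, among them Col1a2 at -0.60 and Tagln at -0.61, and genes past 2-fold such as Tceal5 (1.71) and Wdr7 (-1.43) lie at low levels.

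Of 30 measured stromal fibroblast and extracellular matrix genes, 27 were lower in Capn6-Ko, 20 of them by at least 1.25-fold. Their median difference was -0.44, below all 10000 random lists, whose medians reached -0.094. Tagln and Acta2, which encode the smooth muscle proteins transgelin and α-actin, differed by -0.61 ± 0.074 and -0.60 ± 0.023. The Acta2 value rests on 10 spots per array, with signals of 6937 in Capn6-Wt and 4520 in Capn6-Ko. Col1a2, a chain of type I collagen, differed by -0.60 ± 0.072, and Loxl1, a collagen and elastin cross-linking enzyme, by -0.57 ± 0.079. The Loxl1 value averages a probe at -0.31 (504 in Capn6-Wt, 402 in Capn6-Ko) and one at -0.84 (227 and 126), further apart than the spot error. The 3 members that were not lower were Mgp (0.28 ± 0.11), Thy1 (0.17 ± 0.29) and Mmp13 (0.022 ± 0.13). Lepr was at -0.040 ± 0.055.

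Tagln, Acta2 and Col1a2 were also among the 12 lowest genes above the median level. The others included Actg2, a smooth muscle actin (-0.65 ± 0.090), Fhl2 (-0.61 ± 0.074), Ccn1, a matricellular protein (-0.60 ± 0.078), Itga11, a collagen receptor subunit (-0.60 ± 0.077), and Myl9, a regulatory myosin light chain (-0.60 ± 0.071). Smoc2, a matricellular protein (-0.60 ± 0.076), Grem1, a secreted BMP antagonist (-0.55 ± 0.075), Tm4sf1 (-0.55 ± 0.077) and Mlana, a melanocyte antigen (-0.54 ± 0.090), completed the 12. These values come from single spots except that of Acta2.

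Type I interferon response genes were higher in Capn6-Ko, 19 of 22 measured members, with a median of 0.19 at percentile 100. Oas2, an antiviral oligoadenylate synthetase, was at 0.73 ± 0.081, Ifit3 at 0.66 ± 0.17, Rtp4 at 0.57 ± 0.085 and Oasl2 at 0.41 ± 0.093. Ifi27l2a, an interferon-inducible gene outside the list, was at 0.52 ± 0.082. The list of interferon-gamma response and MHC class II genes had 18 of 23 members higher, with a median of 0.076 at percentile 99.9. Its furthest members all belong to antigen presentation by MHC class II, namely H2-Ab1 (0.53 ± 0.051), H2-Eb1 (0.51 ± 0.074), Cd74, the invariant chain (0.32 ± 0.071), and H2-Aa (0.30 ± 0.087). Ciita, the transactivator of MHC class II genes, was dim and stood at -0.53 ± 0.28.

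Macrophage identity genes were higher by small amounts, beside the stromal median of -0.44. Folr2, a folate receptor of macrophages, had the highest value above the median level, 0.84 ± 0.079, or 1.79-fold. It is not in the macrophage identity list but in that of alternative activation, where 7 of 13 measured members were lower and the median was -0.013. Of the 22 measured members of the macrophage identity list 17 were higher, 4 of them by at least 1.25-fold, with a median of 0.064 at percentile 99.9, led by the fractalkine receptor Cx3cr1 (0.59 ± 0.060), the complement receptor C5ar1 (0.39 ± 0.076), the endotoxin co-receptor Cd14 (0.36 ± 0.069) and Aif1 (0.36 ± 0.073). Chemokine receptor, adhesion and migration genes were higher in 20 of 28, with a median of 0.054 at percentile 99.6. The receptor Ccr2 (0.69 ± 0.16) and the elastase Mmp12 (0.42 ± 0.12) were among the furthest with Cx3cr1. The Mmp12 value averages a bright probe at 0.13 (1479 in Capn6-Wt, 1594 in Capn6-Ko) and a dim one at 0.72 (31.7 and 51.6). Complement and coagulation genes were higher in 18 of 24, with a median of 0.086 at percentile 99.99, with F13a1 at 0.51 ± 0.15, F3 at 0.45 ± 0.25 and Cfb at 0.34 ± 0.20 beside C5ar1. In this list Thbs1 (-0.38 ± 0.077) went the other way, beside the stromal median of -0.44. The F13a1 value averages a bright probe at 0.35 (3177 in Capn6-Wt, 3998 in Capn6-Ko) and a dim one at 0.67 (22.1 and 34.8). The remaining high genes above the median level were Nxt2 (0.65 ± 0.082), Cd72 (0.63 ± 0.050), Efr3b (0.58 ± 0.081), the potassium channel Kcnn4 (0.54 ± 0.076) and Fnbp1l (0.50 ± 0.079).

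Cell cycle genes were higher in 27 of 30 measured members, with a median of 0.12 at percentile 100. Tyms, the thymidylate synthase, was at 0.37 ± 0.19, the replication licensing factor Cdc6 at 0.37 ± 0.15, the topoisomerase Top2a at 0.35 ± 0.10 and the mitotic kinesin Cenpe at 0.27 ± 0.082. Megakaryocyte and platelet markers were higher in 17 of 19, with a median of 0.14 at percentile 100, and Gp6 (0.47 ± 0.15), Gp9 (0.33 ± 0.10) and Gp1ba (0.29 ± 0.12) were among the furthest. Stem and progenitor markers had 9 of 12 higher and a median of 0.11 at percentile 99.0. Among the furthest were Gfi1b (0.28 ± 0.20), Lmo2 (0.21 ± 0.072) and Tal1 (0.16 ± 0.11), while Hoxa7 was at -0.49 ± 0.15, the 1 member past 1.25-fold. Immediate early genes had 15 of 22 higher and a median of 0.11 at percentile 100, with Fos at 0.36 ± 0.026 over 10 spots, Egr2 at 0.22 ± 0.084, Junb at 0.20 ± 0.12 and Nr4a2 at 0.19 ± 0.15. Against the direction of this list, Fosb was at -0.66 ± 0.18 and Fosl1 at -0.54 ± 0.16. By their means, 0.056 and 0.038, the progenitor and immediate early lists did not stand apart.

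Osteoclast genes split, with 9 of 17 higher and a median of 0.066 at percentile 99.0. The fusion genes Dcstamp (0.56 ± 0.11) and Ocstamp (0.41 ± 0.15) and the RANK receptor gene Tnfrsf11a (0.32 ± 0.077) were higher with Fos. With only probes above the median level this median turned to -0.0204.

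The lists of NRF2 targets, of the ER stress and amino acid response and of fatty acid synthesis were lower by small amounts, beside the stromal median of -0.44. Oxidative stress and NRF2 target genes were lower in 16 of 19, with a median of -0.14 below all 10000 random lists. Slc7a11, the cystine transporter, differed by -0.39 ± 0.095, the quinone reductase Nqo1 by -0.29 ± 0.15, the heme oxygenase Hmox1 by -0.25 ± 0.055 and the glutathione synthesis gene Gclm by -0.23 ± 0.080. ER stress and amino acid response genes were lower in 17 of 23, with a median of -0.067 at percentile 0.05. Chac1 (-0.46 ± 0.075), Ddit4 (-0.34 ± 0.080) and the asparagine synthetase Asns (-0.28 ± 0.074) were furthest with Slc7a11. Fatty acid synthesis and lipid storage genes were lower in 12 of 19, with a median of -0.071 at percentile 0.33, and Fads2 (-0.35 ± 0.29), Acaca (-0.30 ± 0.094), Scd1 (-0.19 ± 0.11) and Hilpda (-0.18 ± 0.059) were furthest. Of the 3 Acaca probes, the brightest was at -0.054, with signals of 4251 in Capn6-Wt and 4044 in Capn6-Ko. The other Acaca probes, with Capn6-Wt signals of 76.9 and 60.0, were at -0.21 and -0.65. The lipoprotein lipase gene Lpl of this list was higher, at 0.38. This list did not stand apart by its mean, -0.0345, or after normexp, with a median of -0.0191.

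**Figure D2:**
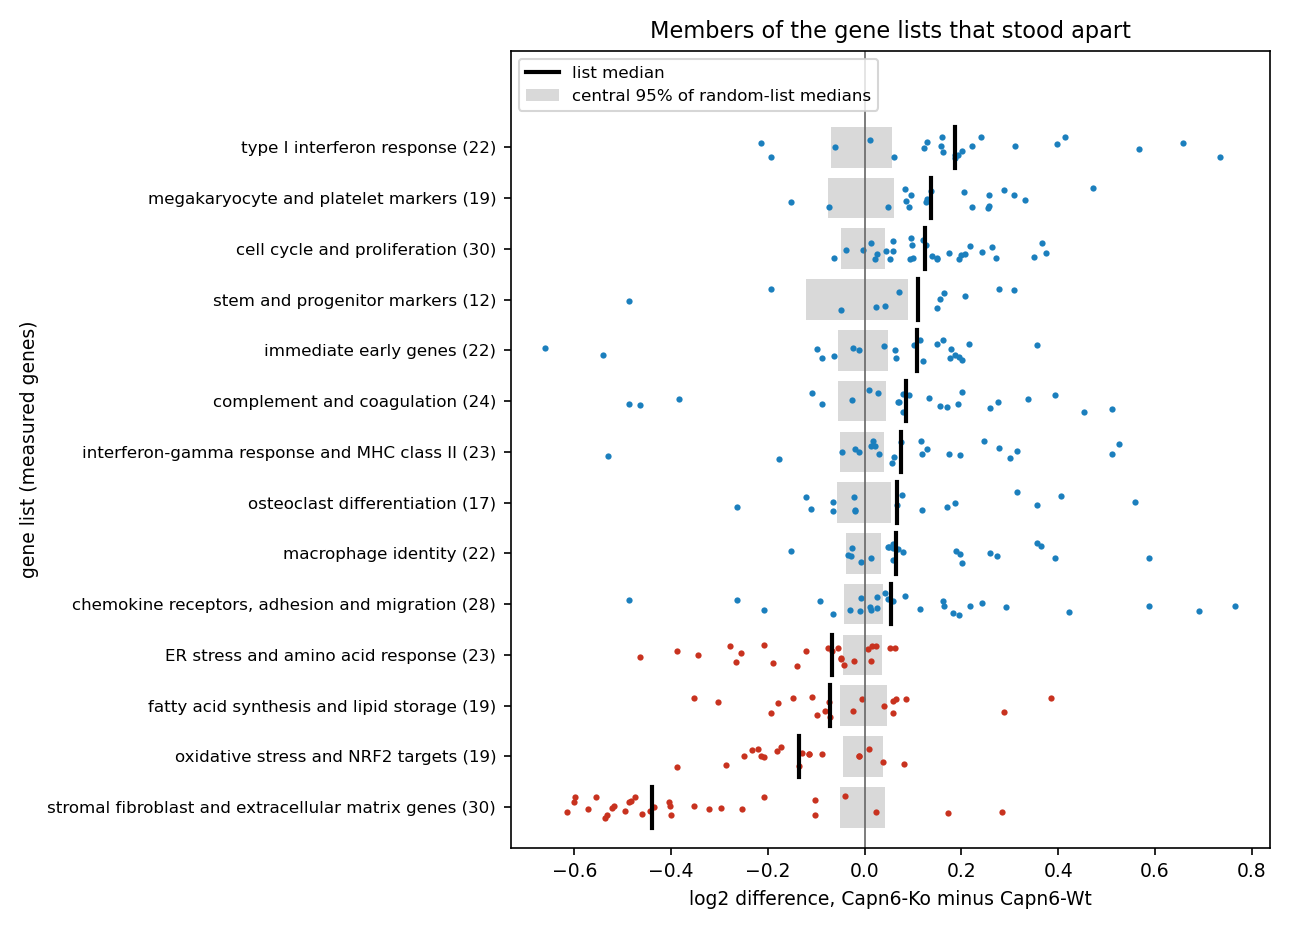
Each row is 1 of 14 gene lists that stood apart, each point the log2 difference, Capn6-Ko minus Capn6-Wt, of a measured member, each black bar the list median, and each grey bar the central 95% of the medians of 10000 random lists matched on level. The stromal list has the lowest median, -0.44, and the type I interferon list the highest, 0.19.

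In all 15 of the 37 lists stood apart, 11 higher and 4 lower, where independent genes would give 1.85, and 1 of the higher lists is not described here. The lists overlap, and 1 pool per group cannot tell genotype from the difference between any pair of cultures.

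Lipid uptake and splicing are themes this knockout has been studied for, and of 5 genes chosen for them 3 were within their spot error. Rac1, a small GTPase, differed by 0.034 ± 0.053, and Cwc22, a splicing factor that loads the exon junction complex, by -0.022 ± 0.061. The scavenger receptor Cd36 was at -0.048 ± 0.074, while the scavenger receptor Msr1 (0.28 ± 0.054) and the cholesterol exporter Abca1 (0.26 ± 0.086) were higher by more than their spot error. Scavenger and lipoprotein receptors as a list had a median of -0.015 over 18 genes at percentile 37.9. The median was 0.015 for cholesterol efflux and LXR targets, -0.025 for cholesterol biosynthesis and -0.0033 for clathrin endocytosis and the lysosome. It was -0.020 for the exon junction complex and -0.030 for the core spliceosome. None of these lists stood apart. A gene value is a mean over its measured probes, which need not cover every transcript form, and probes were not used to compare splice forms.

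Of the calpain family 11 members were measured, with a median of 0.0039 at percentile 62.4. Capn3 (0.40 ± 0.18) and Capn5 (0.37 ± 0.11) were higher and Capn12 (-0.42 ± 0.29) lower by more than 1.25-fold. Capn1 was at -0.16 ± 0.083 and Capn10 at -0.16 ± 0.090. Capn2 (-0.013), Capn7 (0.011), Capn11 (0.0039), Capn15 (0.031), the small subunit Capns1 (0.032) and the calpain inhibitor Cast (-0.019) were within their spot error. Capns2 and 1 of the probes of Capn9 were well above background on the Capn6-Ko array only.

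Markers of most other marrow cells did not stand apart, but some lists had few measured genes, so that a small shift could be missed. Measured were 8 of 23 erythroid, 9 of 26 T and NK cell, 8 of 20 endothelial and 7 of 18 osteoblast and adipocyte markers. Lower in Capn6-Ko were 7 of the 8 erythroid markers (percentile 10.2) and 10 of 12 B and plasma cell markers (percentile 6.9). The median was -0.033 for neutrophil and granulocyte markers, -0.10 for B and plasma cells, -0.024 for T and NK cells, -0.060 for erythroid cells, and 0.074 for mast cells, basophils and eosinophils. It was -0.018 for dendritic cells, -0.035 for endothelial cells and 0.083 for osteoblasts and adipocytes. The NF-kB and TNF response had a median of 0.024 and alternative activation -0.013. The medians were -0.014 for the p53 response, -0.048 for heat shock, -0.020 for hypoxia and glycolysis, -0.035 for oxidative phosphorylation and 0.023 for housekeeping genes.

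By the fixed size of 2-fold, 3 genes were higher and 9 lower in Capn6-Ko, where spot pairs give 11.7 in all, which may be too high. The split was 4 higher and 7 lower after quantile normalization. The 12 genes, named after their values were seen, were Tceal5 (1.71), Fanci (1.25) and Cacna1a (1.08) among the higher, and Wdr7 (-1.43), Igsf3 (-1.36), Lce1g (-1.35), Zfp365 (-1.28), Chst8 (-1.21), Ctxn2 (-1.17), Hdgfl3 (-1.10), Heph (-1.06) and Lce1i (-1.05) among the lower. Each rests on a single spot per array. None was above the median level. A second probe of Cacna1a, well above background on the Capn6-Wt array only, went the other way, with signals of 23.5 in Capn6-Wt and 15.6 in Capn6-Ko.

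A further 371 genes were well above background on the Capn6-Ko array only and 212 on the Capn6-Wt array only. These counts are not cut at the same level. The lowest signal well above background was 16.6 on the Capn6-Wt array and 14.0 on the Capn6-Ko array. Some genes of the Capn6-Ko count were not higher there, such as Mttp, with signals of 21.4 in Capn6-Wt and 18.8 in Capn6-Ko. The bound, which uses the same unlike lowest signals, reached 2-fold for 6 genes of the Capn6-Ko count and 25 of the Capn6-Wt count. In Capn6-Ko the furthest were Olfr1505, at least 7.82-fold higher, Olfr527, at least 4.64-fold, Arpp21, at least 4.31-fold, the interferon-inducible Ifi44l, at least 2.98-fold, and Adam34, at least 2.15-fold. In Capn6-Wt they included Usp50, at least 7.62-fold higher, Sowahb, at least 6.0-fold, Fezf1, at least 5.18-fold, and Olfr728, at least 5.06-fold. Each was read from 1 spot per array.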

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

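Probes without a gene name were used in no comparison of the report, and some carried a signal above that of the control array. Of 10609 such probes well above background on both arrays, 5 were at least 2-fold higher in Capn6-Ko than in Capn6-Wt and 18 at least 2-fold lower, where spot pairs alone would give 26.8 in all. Among the higher, 2 probes of the same unnamed transcript were at 1.06 and 1.32, and a probe for a region on chromosome 3 (51138643 to 51146693, mm9, reverse strand) was at 1.62. The lowest was a probe for a region on chromosome 1 (92412246 to 92423471, mm9, forward strand), at -1.69. These probes were singled out after their values were seen, and no explanation was tested for them.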

How the results depend on the processing

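All 9 further settings of the arrays and both further ways of placing the lists kept the stromal list lower (-0.485 to -0.358) and the type I interferon list higher (0.139 to 0.211), and the lists of NRF2 targets, ER stress, the cell cycle, platelets, macrophage identity, chemokine receptors, complement and MHC class II also stood apart each time. The authors' value table and the median centre differ from the main setting only by a constant per array. These settings could hardly have moved a list, so their agreement adds little. Without a filter on dim probes 312 genes were 2-fold higher and 583 lower, since probes below background then count. With only probes above the median level 0 were higher and 0 lower, since the dim genes are left out. Normexp, chosen after the files were seen, gave 1 higher and 0 lower. The osteoclast list no longer stood apart after normexp (0.0344) or without the filter (0.0235), and turned to -0.0204 with only probes above the median level. The fatty acid list lost its place after normexp (-0.0191) and by its mean (-0.0345), as did the stem and progenitor (0.0558) and immediate early (0.0382) lists by their means. The cause of these losses was not tested. In the other direction, oxidative phosphorylation stood apart in 2 settings, and B cell markers, alternative activation and heat shock in 1 each. Of the named genes' alternative values, 752 lay within the spot error of the reported value and 45 moved further, none of a gene past 1.25-fold to the other sign. Normexp gave most of these moves, with 32 values moved and 61 within the spot error. The median over all genes moved at most to -0.0436, without the filter. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Signal over background limits the dim genes, where the SD of a single-spot difference is 0.29 against 0.075 for bright ones.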

Other observations

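The test of level and the tests on exchanged labels, on stray spots and on the neighbours of Capn6 were chosen or changed after the results they bear on had been seen, and so were the second stromal list, the contractile list and the genes named in the next paragraph.

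The genes named next lie above the median level and passed 1.25-fold, and were picked by hand after their values were seen, with no test of any class of genes. Lower in Capn6-Ko were Csf1, which encodes the macrophage growth factor M-CSF (-0.48), the monocyte chemokines Ccl7 (-0.52) and Ccl2 (-0.42), the protease inhibitor Timp1 (-0.49), Inhba (-0.38) and Gdf15 (-0.37). Higher were the chemokine Ccl9 (0.48), the chitinase-like protein Chil3 (0.48), the acute phase protein Saa3 (0.45) and the lipoprotein lipase Lpl (0.38). These lower genes stood beside a stromal list median of -0.44, a difference of similar size. A list of contractile and actin-binding genes was written after Myl9, Actg2, Fhl2 and Tpm2 had been seen among the lowest, and with these 4 its median was -0.29 over 18 genes. Without them 13 of 14 members were lower, among them Cnn1 (-0.53) and Cnn3 (-0.47), with a median of -0.16, below all 10000 random lists. This is no independent test, because the list was written after the data were seen. Csrp2 (-0.38), also past 1.25-fold above the median level, stayed in it. Of its brightest members, Flna (0.046), Tagln2 (-0.029) and Tpm4 (-0.012) lay near 0.

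Stromal and matrix genes were lower in the Capn6-Ko pool. A bias of the arrays with level is argued against by the lowest of 10000 level-matched random medians, -0.0938, and a position on the slide by the 1153 spots around those of the list, whose median difference was -0.0016. A lower share of stromal cell RNA in that culture may account for it: a second list of stromal genes, with no member in common, had a median of -0.3958 and 27 of 31 members lower (87.1%), yet Pdpn (0.32), Cav1 (0.34), Emilin1 (0.29) and, in the first list, Mgp (0.28) were higher. An equal share of stromal cells that express less of most genes of both lists predicts the same. Cell number and expression per cell therefore stay open, as does an effect of the genotype. Exchanged labels also stay open, because Capn6 was well above background on 0 arrays.

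Of the genes well above background on 1 array only, 31 read from single spots passed a bound of 2-fold. Stray spots could account for them: 4 of 2690 spots of replicated dim probes strayed as far from their own probe, which scales to 29.26 expected among 19678 dim readings, with a 95% Poisson interval of 7.97 to 74.9. A first version of this test left out flagged spots and found 0 of 2574, or 0 expected with an upper limit of 28.2. It was changed after that result was seen, because only replicated probes can be flagged as population outliers, so that the first version removed the spots it looked for. Neither version decides, and a difference between the genotypes in these genes stays open.

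Nxt2, at 0.65, lies near Capn6 on the X chromosome, with 7 protein-coding genes between them. If the genes around Capn6 differed together, by strain sequence carried along with the knockout or by an effect of the deletion on its surroundings, its other neighbours might differ too. The median size of difference of 19 measured neighbours was 0.11, at percentile 87.0 among 12150 windows of neighbouring genes, which falls between the bounds set for and against. Among them only Phf8 (0.33) was past 1.25-fold. Only genes measured on both arrays entered this test, so of the 7 genes between Nxt2 and Capn6 it covers 4. Nxt2 was read from 1 spot per array, and an effect of the genotype on it alone was not tested.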
